A study of Arabidopsis thaliana with 6 samples.

How the data were processed

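The data came from 6 Agilent 2-colour arrays of Arabidopsis thaliana seedlings (accession Col-0, 14 days old). Per the labels' protocols, seedlings grown on agar were moved to deionized water, and then to water holding 20 µM of an analogue of cis-cinnamic acid under light. RNA of seedlings collected after 6 h of treatment was labelled with Cy5 and RNA of control seedlings collected at 0 h with Cy3, so each ratio is treated over control. Groups and replicate numbers were taken from the labels, which give 2 arrays for each of the compounds cis-31, cis-8 and endo-8. The labels call the arrays biological replicates without saying how the seedlings were kept apart, so p-values measure the spread between these samples.

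Per the file headers, the authors deposited the scanner output of Agilent Feature Extraction version 10.5.1.1, while the submitters' processing notes name version 8.5.1.1. Per the file headers, the deposited mean spot and median background intensities of each channel were not normalized. The processed intensities deposited beside them had been background-subtracted, detrended and dye-normalized by the scanner software, per the file headers. The deposited log10 ratio of each spot is red over green processed signal. The series table that the authors deposited held log10 ratios that lay within 0.005 of the scanner output's by spot number on 5 arrays and within 0.0261 on endo-8 array 2 (r above 0.999 on each). It had 13 to 35 empty cells per array and a median of 0 in every column, so its scale, centring and direction were known. No genome was used here; loci were taken from the array annotation in the files and 21861 of the 22086 loci tested were matched by locus to the symbols of the reference table, while the others kept the files' names.

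Intensities were background-corrected with normexp (offset 50) and the log2 ratios were loess-normalized within each array with limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8) and jsonlite 2.0.0 for input and matplotlib 3.10.9 with pandas 2.3.3 for the figures. Control spots had weight 0 in the loess fit and were left out afterwards together with spots marked as outliers, of which an array held 9 to 20. No spot was saturated. Of 43803 probe spots, spots of one probe were averaged, and a locus was represented by its brightest probe. Probes well above background in at least 1 channel on at least 2 arrays were kept, which left 24458 features, 2372 of them probes without a locus. Where a gene was not well above background on any array of a group, its fold is given as a bound ("at least"), computed from normalized log2 values per channel against the lowest signal well above background on each array, and open to dye bias because no dye swap was among these arrays.

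Before the groups were averaged, the arrays were compared. The log2 ratios of the 2 cis-31 arrays differed with an SD of 0.146 over 28232 probes, and repeated spots of 50 probes within those arrays with an SD of 0.143, against 0.443 between the cis-8 arrays and 0.434 between the endo-8 arrays. The cis-31 arrays were therefore averaged and counted as 1 sample. The design written before the data were examined had treated them as 2, and its counts are given beside the others. limma was fitted to these 5 samples with 1 coefficient per compound, which left 2 residual degrees of freedom (prior 2.27), and the lone cis-31 sample was assumed to vary like the others. Each compound was tested against 0, and the mean of the 3 compounds and the differences between compounds were tested as contrasts. Adjusted p-values are Benjamini-Hochberg values over the 24458 features of a contrast, and a gene was called at an adjusted p under 0.05.

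The control channels of cis-8 array 1 and endo-8 array 1 differed with an SD of 0.104 and those of the pair numbered 2 with an SD of 0.112, against 0.427 to 0.435 between controls of different numbers, so cis-8 and endo-8 arrays of one number carried control RNA that differed little. The fit treats these arrays as independent, so p-values of the mean of the 3 compounds leave out what their controls share. Likewise the test between cis-8 and endo-8 does not take that shared part out of its spread. Correlation from such shared controls was simulated 100 times, with equal and independent noise in the treated and control channels. The cis-31 arrays lay on slide 1 in scan 1 and the other arrays on slide 2 in scan 2, so compound, slide, scan and control RNA cannot be told apart for cis-31 against the others.

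A total of 25 gene lists with 480 entries was fixed before the data were examined. They cover early auxin genes of the Aux/IAA and GH3 families, SAUR genes, lateral root LBD genes with auxin response factors, auxin transport, auxin biosynthesis and turnover, ethylene, jasmonate, salicylate, abscisic acid, cytokinin, gibberellin with brassinosteroid, phenylpropanoid and flavonoid pathways, xenobiotic detoxification, morning and evening clock genes, hypoxia, sugar starvation, heat shock, expansins with xyloglucan endotransglucosylases, the mitotic cell cycle, nutrient supply, and markers of green tissue, root, and shoot meristem with stomatal lineage. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, and adjusted over the 25 lists of a contrast. Named genes followed a rule set at the same time: the 12 highest and 12 lowest changes of the mean, the 5 highest and 5 lowest of each compound, the 10 highest and 10 lowest of each difference with no overlap between arrays, and up to 4 called members of a list, with textbook members given by value where they were not called; the text takes its examples from these.

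The gene and list tests were checked on simulated data over 24447 genes with 200 changed. With planted changes of 1, 2 and 4 log2 units, the share recovered was 0%, 68.7% and 89.4% for cis-31, 28.4%, 89.6% and 97.0% for cis-8, and 16.4%, 89.6% and 97.0% for endo-8, with 11, 8 and 7 false calls. A SAUR list raised by 1 log2 unit with endo-8 gave an adjusted p of 3.67e-32 by camera and of 0.146 with an estimated correlation, and 0 of the 24 other lists were called by camera. Genes were drawn independently in that simulation, so it cannot show how often camera falsely calls lists whose members correlate. The test with an estimated correlation missed the planted rise, so its lack of a call does not decide whether a list changed. Alternatives tried were the scanner's processed signals, no background subtraction, median centring, no filter and a stricter filter, the mean of a gene's probes, a trended robust prior, the replicate number as a block, each array left out, the arrays of 1 compound or slide alone, and the table of ratios deposited for the series. Spots well above background made up 67.7% to 71.9% of probe spots in Cy3 and 69.8% to 72.8% in Cy5.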

Results

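Gene expression was measured in whole Arabidopsis seedlings after 6 h in 20 µM of 1 of 3 analogues of cis-cinnamic acid, a plant growth inhibitor. The labels name the compounds cis-31, cis-8 and endo-8. Each of the 6 arrays set a treated sample (Cy5) against control seedlings taken at 0 h (Cy3). The comparisons asked which transcripts changed with each compound and where the compounds differed. Changes are log2 ratios. Values of cis-8 and endo-8 come from n = 2 arrays and are given ± SD or with a standard error (SE). Values of cis-31 come from n = 1 sample, the mean of 2 arrays that differed about as much as repeated spots of one probe. Standard errors and p-values of cis-31 rest on the spread of the cis-8 and endo-8 arrays. Untreated seedlings kept for 6 h and dye-swapped arrays were not analysed here, so time of day, transfer to water and dye lie within every change against the control.

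Early auxin-response genes rose with cis-31. GH3.3 (AT2G23170), an enzyme that joins auxin to amino acids, rose by 7.66 (SE 0.19, adjusted p = 0.00795). The auxin-induced repressor gene IAA5 (AT1G15580) rose by 6.71 (SE 0.42, adjusted p = 0.01), and the auxin-responsive family pseudogene AT1G11803 by 5.65 (SE 0.27). All 17 SAUR genes, a family of small auxin-induced transcripts linked to cell expansion, rose (17 adjusted over the list alone), with a median of 4.37; SAUR22 rose by 5.56 (SE 0.22). The SAUR list gave an adjusted p of 2.23e-17 by camera, 0.0104 by fry and adjusted p = 0.315 with an estimated correlation. Of 31 measured Aux/IAA and GH3 genes 18 rose, 0 fell and 13 were not called (23 higher and 2 lower adjusted over the list alone). That list gave 6.84e-12 by camera, 0.0137 by fry and adjusted p = 0.315 with an estimated correlation. SAUR signal of the cis-31 arrays differed from that of the other arrays by a median of 2.07 in the treated channel and -1.37 in the control channel. The lateral root LBD and auxin response factor list of 12 genes also holds HAT2, PUCHI and GATA23. Of its members 1 rose (2 adjusted over the list alone), the auxin-induced HAT2 by 3.55 (SE 0.14). The list had a median of -0.08 and a mean of 0.41, with an upward test direction (adjusted p = 0.513 by camera). LBD16 was at 0.49 (adjusted p = 0.262 by limma).

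Heat shock, jasmonate and detoxification genes were also higher with cis-31. Of 14 heat shock genes 10 rose, HSP101 by 3.77 (SE 0.26), and the heat shock factor gene HSFA7A fell by 1.78 (SE 0.22). Adjusted over the list alone 11 were higher and 1 lower, with 3.94e-07 by camera, 0.0196 by fry and adjusted p = 0.315 with an estimated correlation. Of 25 jasmonate genes 12 rose and 0 fell (18 higher adjusted over the list alone), among them the jasmonate synthesis genes AOS at 2.82 (SE 0.46) and OPR3 at 2.56 (SE 0.25). Camera gave the jasmonate list 9.88e-09 and fry 0.0523, and adjusted p = 0.405 with an estimated correlation. Detoxification genes rose in 15 of 36 members (22 higher and 6 lower adjusted over the list alone), with the transporter gene ABCG40 at 5.88 (SE 0.51). That list gave 1.6e-05 by camera and adjusted p = 0.481 with an estimated correlation. Abscisic acid and drought genes rose in 4 of 23 members (6 adjusted over the list alone), including ABI2 at 3.05 (SE 0.21), with 0.00047 by camera and adjusted p = 0.315 with an estimated correlation. Expansins and xyloglucan endotransglucosylases, which act on cell walls, rose in 7 of 26 members (8 higher and 2 lower adjusted over the list alone), EXPA10 by 2.69 (SE 0.17). Camera gave them 0.00267, with adjusted p = 0.315 with an estimated correlation.

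The largest falls with cis-31 included defence-related genes. AT4G12490, a lipid transfer protein family gene, fell by 6.45 (SE 0.64, adjusted p = 0.018). FRK1, a receptor-like kinase gene induced by bacterial flagellin, fell by 6.44 (SE 0.64, adjusted p = 0.0182). The nitrate transporter gene NRT2.5 fell by 5.47 (SE 0.33), with Cy5 well above background on 1 of 2 arrays, CHX16 fell by 5.28 (SE 0.44) and the chitinase gene AT2G43620 fell by 5.16 (SE 0.21). In the control channel FRK1 lay 3.79 and NRT2.5 lay 4.13 above the controls of the other arrays. Sugar starvation genes fell in 6 of 16 members (13 adjusted over the list alone), BGAL4 to -3.58 (SE 0.29) and SEN1 to -3.47 (SE 0.62). They gave 3.94e-07 by camera and adjusted p = 0.532 with an estimated correlation. Salicylate genes fell in 4 of 18 members, FMO1 to -3.25 (SE 0.39), and GRX480 rose by 3.51 (SE 0.24), with 0.0159 by camera and adjusted p = 0.532 with an estimated correlation. Salicylate signal of the cis-31 arrays differed from that of the other arrays by a median of -0.67 in the treated channel and 0.79 in the control channel. Green tissue markers rose in 5 of 21 members (11 adjusted over the list alone) and root markers fell in 1 of 20 (4 adjusted over the list alone). These marker lists gave 6.58e-05 and 0.000121 by camera, and adjusted p = 0.315 each with an estimated correlation. Of 25 lists camera called 16 with cis-31, fry 8 and both 7.

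Over all genes 1521 rose and 904 fell with cis-31. Counting its arrays as 2 samples gave 5771 higher and 5049 lower, the deposited series table gave 1482 calls, and 1430 genes were called without either cis-8 array and 1192 without either endo-8 array.

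With cis-8 the auxin conjugation gene GH3.3 rose by 5.51 ± 0.25 (adjusted p = 0.0223), GH3.2 by 2.96 ± 0.51 (adjusted p = 0.0460, control well above background on 1 of 2 arrays) and IAA19 by 1.60 ± 0.16 (adjusted p = 0.0494). They were the 3 of 31 Aux/IAA and GH3 genes called (14 higher and 2 lower adjusted over the list alone), with 0.000703 by camera and adjusted p = 0.852 with an estimated correlation. SAUR genes had a median of -0.12 and a mean of 0.03, with an upward test direction (adjusted p = 0.915 by camera). By limma 0 of the 17 were called over all genes or adjusted over the list alone, and SAUR22 was at -0.43 ± 0.34. The LBD and auxin response factor list had a median of 1.66, and the lateral root genes PUCHI at 2.42 ± 0.41 and LBD16 at 1.95 ± 0.01 rose (10 of 12 adjusted over the list alone). It gave 8.93e-07 by camera and adjusted p = 0.852 with an estimated correlation. The aldo-keto reductase family gene AT1G60750 rose by 3.42 ± 0.13, the lipid transfer protein gene LTP2 by 2.99 ± 0.04 and the chitinase gene AT2G43620 by 2.96 ± 0.35. The peroxidase gene AT3G01190 fell to -3.26 ± 0.53, the signalling peptide gene CLE2 to -3.24 ± 0.11 (Cy5 well above background on 1 of 2 arrays) and the transferase family gene AT4G15390 to -3.19 ± 0.59 (other probe -1.46). The transcription factor gene ORA47 fell to -3.169 ± 0.30, and the peroxidase gene AT1G49570 fell to -2.87 ± 0.46.

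With cis-8, detoxification genes rose in 2 of 36 members (5 adjusted over the list alone), GSTU22 by 2.46 ± 0.44, with 2.73e-05 by camera and adjusted p = 0.852 with an estimated correlation. Mitotic cell cycle genes had a median of -0.56, with 0 of 16 called by limma over all genes and 13 lower adjusted over the list alone. They gave 3.78e-07 by camera and adjusted p = 0.852 with an estimated correlation. Root markers had a median of -0.42, and PRP3 fell as 1 of 20 (5 lower adjusted over the list alone). Green tissue markers had a median of 0.25, with 0 of 21 called by limma (3 higher adjusted over the list alone). Sugar starvation genes had a median of -0.37 (0.10 on array 1 and -0.86 on array 2) with 0 of 16 called by limma (0 adjusted over the list alone), 0.0122 by camera and adjusted p = 0.942 with an estimated correlation. Green tissue and root markers each gave 0.000876 by camera and adjusted p = 0.715 with an estimated correlation. Of 25 lists camera called 10 with cis-8 and fry 0, with 0.187 by fry for the Aux/IAA and GH3 list.

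Over all genes 141 rose and 161 fell with cis-8. Median centring gave 4567 higher and 917 lower, with the median of all genes at 0.21, the scanner's processed signals 32 higher and 58 lower, and counting the cis-31 arrays as 2 samples 4120 calls. The deposited series table gave 8, no filter 482, the stricter filter 103, a trended robust prior 144 and the replicate number as a block 1622. By limma 0 genes passed without cis-8 array 1, cis-8 array 2, endo-8 array 1 or endo-8 array 2, with 3561, 4031, 5898 and 5898 at an unadjusted p under 0.05.

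With endo-8 the early auxin genes rose broadly. GH3.3 rose by 7.04 ± 0.17 (adjusted p = 0.00854), IAA5 by 5.46 ± 0.73, GH3.2 by 5.15 ± 0.50 (control well above background on 1 of 2 arrays), IAA29 by 4.75 ± 0.26 and GH3.1 by 4.38 ± 0.24. Of 31 Aux/IAA and GH3 genes 22 rose and 0 fell (23 adjusted over the list alone), with 1.02e-14 by camera, 0.0142 by fry and adjusted p = 0.371 with an estimated correlation. Of 17 SAUR genes 16 rose (17 adjusted over the list alone), SAUR22 by 2.34 ± 0.19, with a median of 2.201, 1.38e-15 by camera, 0.0142 by fry and adjusted p = 0.371 with an estimated correlation. In the LBD and auxin response factor list 8 of 12 members rose (10 adjusted over the list alone), LBD17 by 3.96 ± 0.79, GATA23 by 3.78 ± 0.19 and PUCHI by 3.54 ± 0.43. They gave 1.41e-08 by camera and adjusted p = 0.371 with an estimated correlation. Ethylene genes rose in 7 of 24 members (13 adjusted over the list alone), with the ethylene synthesis genes ACS8 at least 17.0-fold and ACS4 at least 9.65-fold higher. That list gave 2.91e-07 by camera and adjusted p = 0.371 with an estimated correlation.

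Cell division and root genes were lower with endo-8. Of 16 mitotic cell cycle genes 14 fell (16 adjusted over the list alone), the mitotic activator gene CDC20.1 to -1.85 ± 0.31 and the cytokinesis gene KNOLLE to -1.75 ± 0.26. Camera gave the mitotic list 6.11e-12, with adjusted p = 0.377 with an estimated correlation. Root markers fell in 10 of 20 members (14 adjusted over the list alone), the root hair gene COBL9 to -3.14 ± 0.46 and the Casparian strip gene CASP1 to -2.74 ± 0.68. Root markers gave 1.6e-08 by camera and adjusted p = 0.371 with an estimated correlation, and green tissue markers had a median of 0.19 with 0.0274 by camera and adjusted p = 0.371 with an estimated correlation. The lowest single genes were AT5G57625 at -4.11 ± 0.58 (other probe -3.47), the peroxidase gene AT1G05250 at -3.95 ± 0.60, GH9C1 at -3.51 ± 0.18 (Cy5 well above background on 1 of 2 arrays), the water channel gene TIP2;3 at -3.44 ± 0.67 (other probe -2.37) and AT4G15390 at -3.39 ± 0.47 (other probe -1.49). Detoxification genes rose in 11 of 36 members (25 adjusted over the list alone), the glutathione transferase gene GSTU25 by 3.87 ± 1.07, with 8.21e-10 by camera and adjusted p = 0.371 with an estimated correlation. Heat shock genes rose in 4 of 14 members (11 higher and 1 lower adjusted over the list alone), HSP90.1 by 1.36 ± 0.13, with 2.03e-05 by camera and adjusted p = 0.371 with an estimated correlation. Sugar starvation genes rose in 1 of 16 members (1 adjusted over the list alone), GDH2 by 1.202 (SE 0.18), with 0.0274 by camera and adjusted p = 0.634 with an estimated correlation. Salicylate genes rose in 4 of 18 members (5 adjusted over the list alone), GRX480 by 2.70 ± 0.23, with 0.00204 by camera and adjusted p = 0.377 with an estimated correlation. Of 25 lists camera called 14 with endo-8, fry 10 and both 7; detoxification and salicylate genes gave 0.0687 by fry.

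Over all genes 1043 rose and 1275 fell with endo-8. Median centring gave 6925 higher and 2367 lower, with the median of all genes at 0.22, counting the cis-31 arrays as 2 samples gave 6694 calls, and 1048 genes were called without either cis-8 array. The scanner's processed signals gave 1287 and the deposited series table gave 1086. By limma 0 passed without endo-8 array 1 or array 2, with 5315 and 4396 at an unadjusted p under 0.05.

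**Figure D1:**
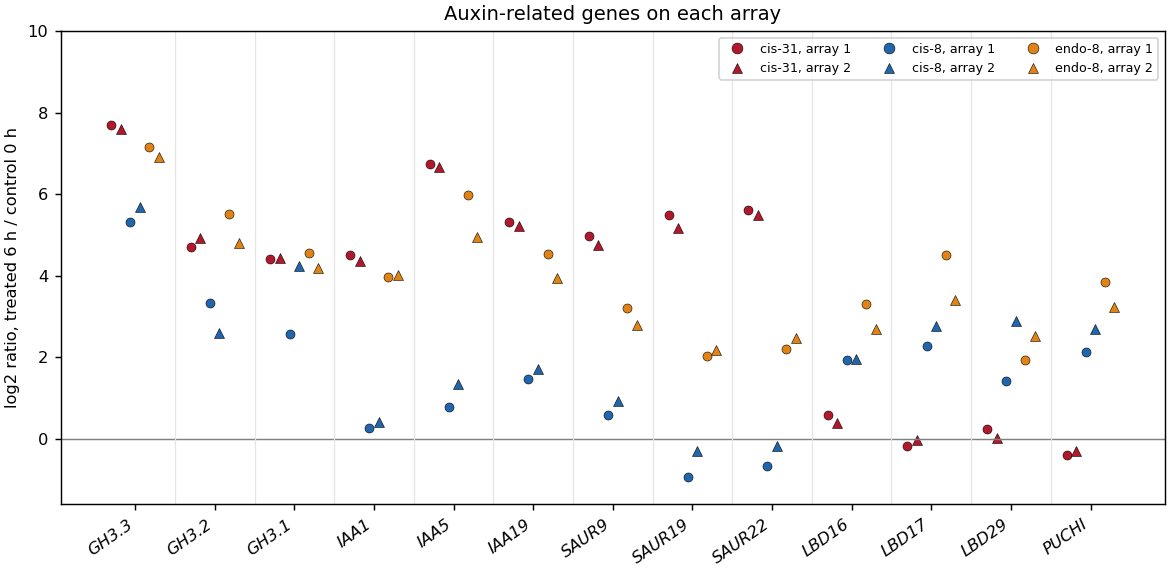
Log2 ratio of treated (6 h) over control (0 h) seedlings for auxin-related genes, with one point per array. SAUR22 stood at 5.56 with cis-31 and at -0.43 with cis-8.

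**Figure D2:**
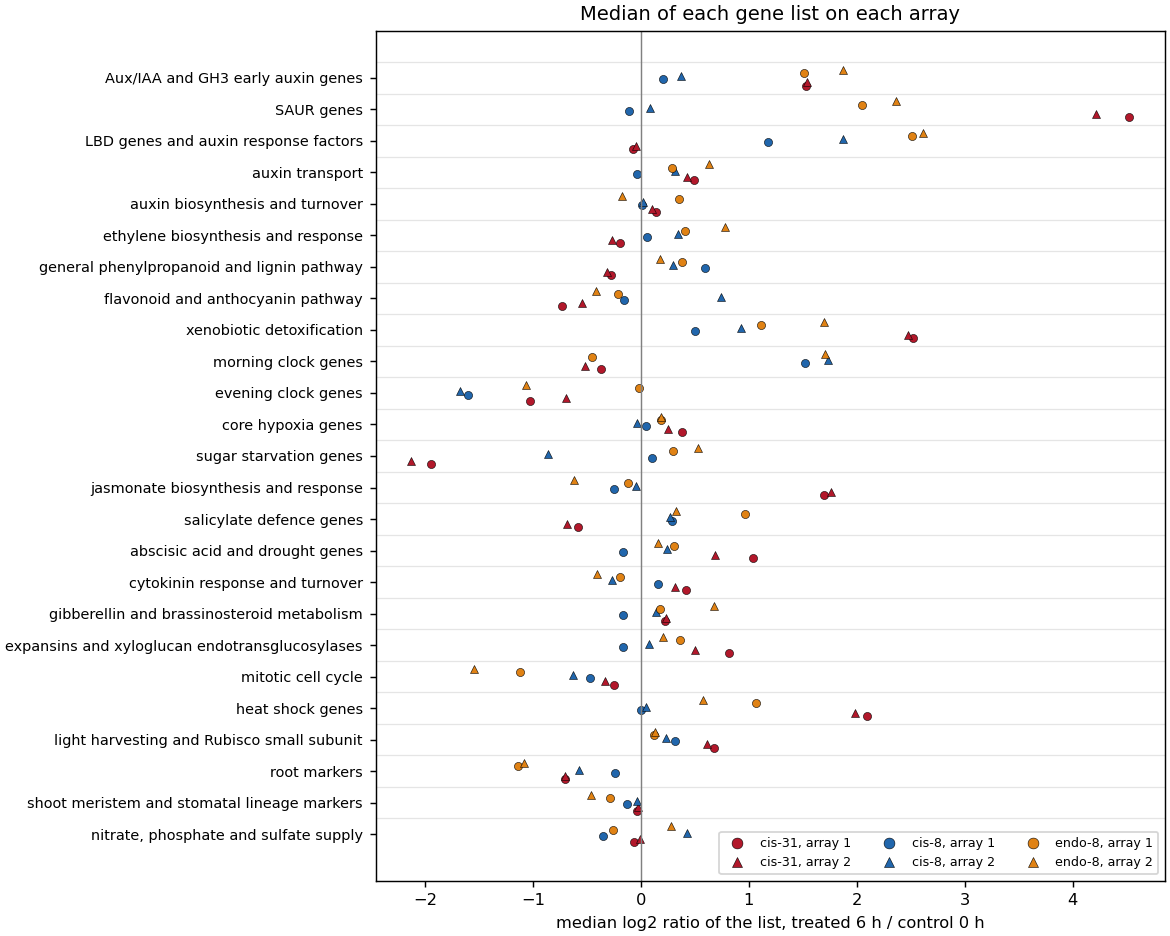
Median log2 ratio of gene lists on each array. The SAUR list stood at 4.52 and 4.22 on the cis-31 arrays, at -0.11 and 0.09 on the cis-8 arrays and at 2.05 and 2.37 on the endo-8 arrays.

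Averaged over the 3 compounds, early auxin genes were among the 12 highest and peroxidase genes and a root hair gene among the 12 lowest. GH3.3 rose by 6.73 (SE 0.09, adjusted p = 0.00182), IAA5 by 4.41 (SE 0.20), GH3.2 by 4.31 (SE 0.17), GH3.1 by 4.07 (SE 0.28), IAA19 by 3.71 (SE 0.11) and IAA29 by 3.63 (SE 0.14). Controls were well above background on 5 of 6 arrays for IAA5 and GH3.1 and on 4 of 6 for GH3.2. The phosphatase gene AT5G02760 followed at 3.43 (SE 0.08), then GSTU25 at 3.39 (SE 0.37), GSTU24 at 3.195 (SE 0.44), AT1G60750 at 3.13 (SE 0.07), MAKR6 at 3.05 (SE 0.25) and AT3G16330 at 3.01 (SE 0.23). Lowest were the peroxidase gene AT1G05250 at -3.55 (SE 0.43), AT5G57625 at -3.14 (SE 0.40; other probe -2.51), the root hair gene RHS13 at -2.84 (SE 0.28), AGP3 at -2.84 (SE 0.35), AT4G26010 at -2.70 (SE 0.41) and AT1G52050 at -2.67 (SE 0.17). AT4G33980 at -2.53, AT5G19890 at -2.45, GSTF14 at -2.41, AT4G15390 at -2.33 (other probe -1.13), AT3G01190 at -2.32 and AT5G04960 at -2.31 came next. AT4G33980 is the evening gene COR28, at -0.29 and -2.29 on the endo-8 arrays, -2.65 and -3.87 on the cis-8 arrays and -3.23 and -2.84 on the cis-31 arrays. Aux/IAA and GH3 genes rose in 24 of 31 members and fell in 2, IAA27 and IAA28 (25 and 2 adjusted over the list alone), and all 17 SAUR genes rose (17 adjusted over the list alone). SAUR medians by array were 4.52 and 4.22 with cis-31, -0.11 and 0.09 with cis-8, and 2.05 and 2.37 with endo-8. The SAUR rise thus did not hold for cis-8. Detoxification genes rose in 20 of 36 members (26 adjusted over the list alone) and root markers fell in 10 of 20 (16 adjusted over the list alone). In that order the lists gave 2.83e-13, 6.29e-16, 1.75e-10 and 2.65e-08 by camera, and adjusted p = 0.382 each with an estimated correlation. Mitotic cell cycle genes fell in 14 of 16 members (15 adjusted over the list alone), with 9.24e-10 by camera, 0.0339 by fry and adjusted p = 0.459 with an estimated correlation. Evening clock genes fell in 5 of 11 (10 adjusted over the list alone) and sugar starvation genes in 5 of 16 (10 lower and 1 higher adjusted over the list alone). They gave 2.61e-05 and 0.0001 by camera, with adjusted p = 0.5 and adjusted p = 0.536 with an estimated correlation. Sugar starvation medians by array were -1.94 and -2.12 with cis-31, 0.10 and -0.86 with cis-8, and 0.30 and 0.53 with endo-8, so the fall did not hold for each compound. Green tissue markers rose in 8 of 21 members (14 adjusted over the list alone), with 1.36e-06 by camera and adjusted p = 0.382 with an estimated correlation. Of 25 lists camera called 15, fry 11 and both 10; evening clock and sugar starvation genes gave 0.0892 and 0.142 by fry.

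Over all genes 2188 rose and 1943 fell in this mean. Median centring gave 7325 higher and 1957 lower, with the median of all genes at 0.15, and counting the cis-31 arrays as 2 samples gave 10487 calls. The count was 1355 without cis-8 array 1, 1090 without cis-8 array 2, 1770 without endo-8 array 1 and 1337 without endo-8 array 2.

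The compounds cis-8 and endo-8 shared slide, dose and hours of treatment, and the SAUR and the Aux/IAA and GH3 lists were lower with cis-8. SAUR genes differed by a median of -2.30 (15 of 17 lower adjusted over the list alone), with 8.69e-23 by camera, 0.0493 by fry and adjusted p = 0.322 with an estimated correlation. Aux/IAA and GH3 genes differed by a median of -1.46 (21 of 31 lower adjusted over the list alone), with 3.97e-21 by camera, 0.0493 by fry and adjusted p = 0.322 with an estimated correlation. IAA5 differed by -4.40 (95% interval -5.54 to -3.25), IAA1 by -3.66 (-4.01 to -3.31), SAUR22 by -2.76 (-3.36 to -2.16) and GH3.3 by -1.53 (-2.04 to -1.02). For GH3.1 the difference was -0.97 (-2.56 to 0.63) and for LBD29 it was -0.07 (-1.59 to 1.44). Mitotic genes were higher with cis-8 by a median of 0.78 (14 of 16 adjusted over the list alone), with 1.31e-10 by camera, 0.165 by fry and adjusted p = 0.39 with an estimated correlation. Evening clock genes were lower with cis-8 (4.23e-06 by camera, adjusted p = 0.39 with an estimated correlation) and morning clock genes higher (0.0424 by camera, adjusted p = 0.609 with an estimated correlation). In both clock lists endo-8 array 1 stood apart from endo-8 array 2, with morning medians of -0.45 and 1.71. Of 25 lists camera called 18 and fry 3. By limma 0 genes passed over all genes, with 2994 at an unadjusted p under 0.05 against 1222.9 from chance and a smallest adjusted p of 0.122, that of IAA1. That test took the arrays as unpaired. With the replicate number as a block limma called 0 too, with 4191 at an unadjusted p under 0.05. With the cis-31 arrays as 2 samples 16 genes were higher and 58 lower.

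Between cis-31 and the other compounds, the largest differences included defence and auxin genes. FRK1 was higher with cis-8 than with cis-31 by 9.65 (95% interval 7.51 to 11.79) and with endo-8 by 9.10 (6.96 to 11.24). The lipid transfer protein family gene AT4G12490 differed by 10.16 (8.04 to 12.27) and 8.72 (6.60 to 10.83), and the chitinase gene AT2G43620 by 8.12 (7.41 to 8.83) and 7.26 (6.55 to 7.97). The stress-related transcription factor gene WRKY40 was lower by -6.88 with cis-8 (-8.95 to -4.81) and by -5.25 with endo-8 (-7.32 to -3.18), and SIB1 by -5.83 (-7.01 to -4.65) and -5.30 (-6.48 to -4.13). HRE2 differed by -5.14 (-6.08 to -4.21) and -4.66 (-5.60 to -3.73). The control channel of the cis-31 arrays lay above that of the other arrays by 3.79 for FRK1, 3.21 for AT4G12490 and 3.76 for AT2G43620, and the treated channel differed by -5.58, -6.23 and -3.93. For WRKY40, SIB1 and HRE2 the control channel differed by -1.53, 0.41 and 0.44 and the treated channel by 4.53, 5.97 and 5.35. SAUR genes were lower in 15 of 17 members with cis-8 (16 adjusted over the list alone; median -4.10) and in 11 with endo-8 (13 adjusted over the list alone; median -2.00). They gave 2.44e-15 and 4.85e-08 by camera and 0.0188 and 0.067 by fry, with adjusted p = 0.595 and adjusted p = 0.555 with an estimated correlation. Aux/IAA and GH3 genes were lower in 11 of 31 members with cis-8 (17 adjusted over the list alone), with 3.16e-08 by camera and adjusted p = 0.595 with an estimated correlation. With endo-8 that list had a median difference of -0.05 (adjusted p = 0.68 by camera), with IAA29 at -0.15 (-1.13 to 0.82) and GH3.2 at 0.33 (-0.89 to 1.55).

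Over all genes 651 were higher and 900 lower with cis-8 than with cis-31, and 783 higher and 965 lower with endo-8. Median centring gave 1240 higher and 835 lower, and 1721 higher and 1000 lower, and counting the cis-31 arrays as 2 samples gave 8885 and 9731 calls. In the same order the scanner's processed signals gave 834 and 561, and the deposited series table gave 696 and 420. By limma 0 passed for cis-8 without cis-8 array 1 or array 2 (5085 and 6248 at an unadjusted p under 0.05), and 737 without either endo-8 array. For endo-8, 0 passed by limma without endo-8 array 1 or array 2 (6674 and 5652 at an unadjusted p under 0.05), and 436 without either cis-8 array. Slide, scan and control RNA changed together with cis-31 and cannot be told apart from it.

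**Figure D3:**
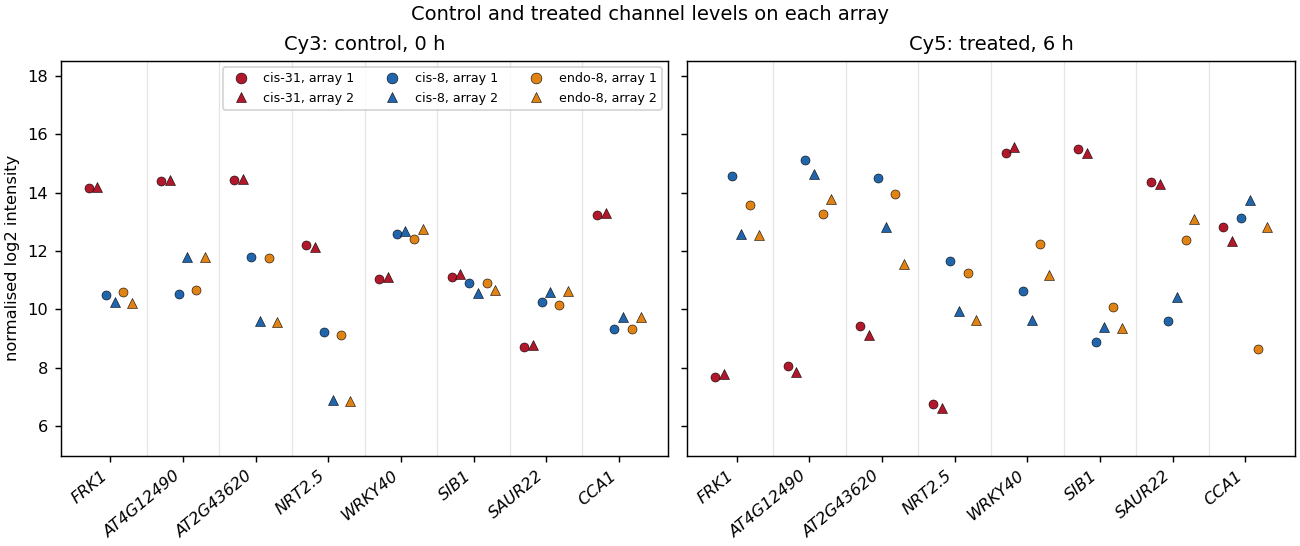
Normalized log2 signal of treated (Cy5) and control (Cy3) channels by array for defence, transport, auxin and clock genes. FRK1 lay at 14.17 in the cis-31 controls and at 10.38 in the others.

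Across 24458 features the log2 changes of cis-8 and endo-8 correlated with r = 0.678 (covariance 0.173), against r = 0.501 (covariance 0.0153) in 100 simulations of the shared controls alone. The simulation gave treated and control channels equal and independent noise, which by itself sets its r near 0.501. It therefore gives no chance level for the observed r. The cis-8 and endo-8 calls shared 94 higher genes (6.01 if independent) and 124 lower (8.39 if independent). Part of that excess may come from the controls, and the calls were not split by control. Arrays of different number, whose controls differed more, correlated at 0.634 for cis-8 array 1 with endo-8 array 2. For cis-8 array 2 with endo-8 array 1 the value was 0.363. Arrays numbered 1 correlated at 0.663 and those numbered 2 at 0.599, against 0.626 between the cis-8 arrays and 0.718 between the endo-8 arrays. For cis-31 and cis-8, r was 0.00396, and for cis-31 and endo-8 it was 0.0960. The cis-31 arrays had their own slide, scan and controls, and morning clock genes lay higher in those controls by a median of 1.23. A low r with cis-31 therefore does not by itself show unlike responses to the compounds. The cis-31 and endo-8 calls shared 314 higher genes (64.9 if independent) and 63 lower (47.1 if independent), with 153 opposite (118 if independent). Those of cis-31 and cis-8 shared 21 higher and 31 lower (8.77 and 5.95 if independent), with 79 opposite (15.2 if independent). All 3 compounds called 15 genes higher, among them GH3.3, GH3.2 and IAA19, and 22 lower, among them the clock gene GI. With cis-8, GH3.3 passed at an adjusted p of 0.0223 by limma, but GH3.2, IAA19 and GI narrowly, at 0.0460, 0.0494 and 0.0455. GI passed narrowly with endo-8 too, at 0.0494. These shared calls hang on the threshold, and the deposited series table gave 8 calls with cis-8.

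Clock genes differed between arrays of one compound. RVE1, a morning-phased gene, was at 2.27 and 1.68 on the cis-8 arrays and at -1.18 and 1.88 on the endo-8 arrays. CCA1, a morning clock gene, was at 3.78 and 4.01 on the cis-8 arrays and at -0.69 and 3.096 on the endo-8 arrays. Morning clock genes had a median of 1.73 with cis-8 (6 of 12 higher and 1 lower adjusted over the list alone), with 0.0133 by camera and adjusted p = 0.942 with an estimated correlation. Evening clock genes had a median of -1.77 with cis-8, and GI fell to -1.28 (11 of 11 lower adjusted over the list alone), with 3.78e-07 by camera and adjusted p = 0.852 with an estimated correlation. With cis-31 the evening median was -0.89 (adjusted p = 0.014 by camera, adjusted p = 0.649 with an estimated correlation) and with endo-8 it was -0.59 (adjusted p = 0.0331 by camera, adjusted p = 0.634 with an estimated correlation). The evening medians of the endo-8 arrays were -0.02 on array 1 and -1.06 on array 2.

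**Figure D4:**
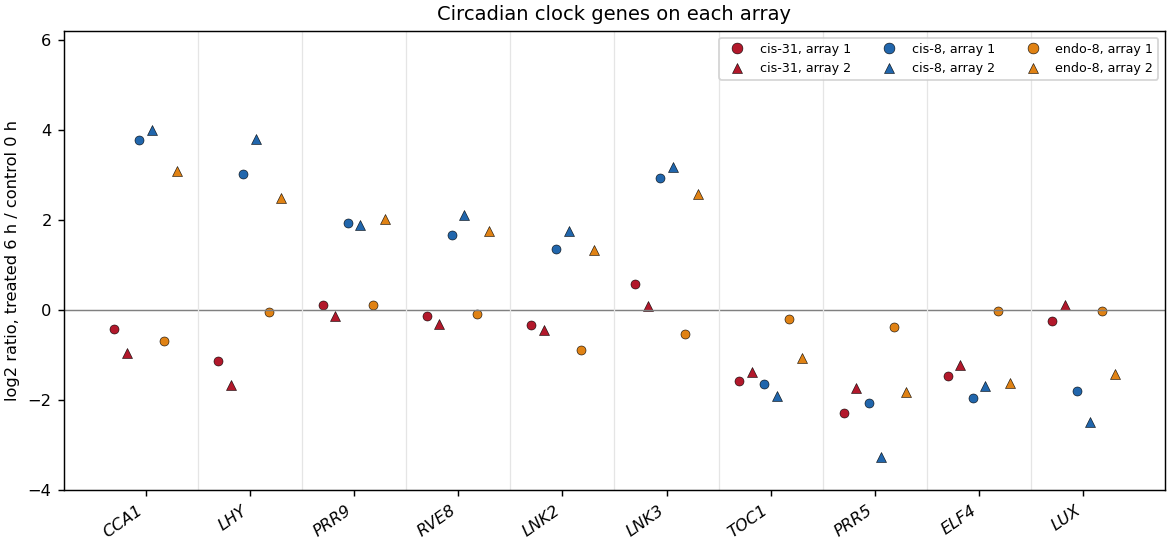
Log2 ratio of morning and evening clock genes on each array. CCA1 stood at -0.69 on endo-8 array 1 and at 3.096 on endo-8 array 2.

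Auxin transport genes rose in 2 of 17 members with cis-31, LAX2 by 2.17 (SE 0.22) and PIN3 by 1.28 (SE 0.22), and in 3 with endo-8, with 0.0159 and 0.0101 by camera and adjusted p = 0.649 and adjusted p = 0.596 with an estimated correlation. Phenylpropanoid and lignin genes fell in 2 of 18 members with cis-31, CAD4 to -1.95 (SE 0.23) and COMT1 to -1.55 (SE 0.21), with 0.0443 by camera and adjusted p = 0.649 with an estimated correlation. With cis-8 that list lay the other way, at a median of 0.43 (5 higher adjusted over the list alone), with 0.00359 by camera and adjusted p = 0.907 with an estimated correlation. Flavonoid genes fell in 3 of 16 members with cis-31, among them the chalcone synthase gene CHS to -1.82 (SE 0.25), with 0.0211 by camera and adjusted p = 0.649 with an estimated correlation. Flavonoid signal of the cis-31 arrays differed from that of the other arrays by a median of 0.12 in the treated channel and 0.82 in the control channel. For phenylpropanoid and lignin genes these medians were -0.19 and 0.54. Gibberellin and brassinosteroid genes rose in 5 of 18 members with endo-8, GA2ox6 by 1.37 (SE 0.11), with 0.0373 by camera and adjusted p = 0.377 with an estimated correlation. Hypoxia genes rose in 3 of 18 members and fell in 2 with cis-31, HRE2 rising by 5.54 (SE 0.28), with 0.0508 by camera, 0.0315 by fry and adjusted p = 0.415 with an estimated correlation. Shoot meristem and stomatal lineage markers fell in 4 of 9 measured members with endo-8, EPF2 to -1.67 (SE 0.30), and KNAT1 rose by 1.39 (SE 0.13), with 0.171 by camera, 0.035 by fry and adjusted p = 0.449 with an estimated correlation. With cis-31, endo-8 and cis-8 in turn, camera gave 0.564, 0.803 and 0.847 for auxin biosynthesis and turnover. It gave 0.564, 0.175 and 0.433 for cytokinin genes, and 0.725, 0.803 and 0.915 for nutrient supply. Median, mean and test direction differed in sign for ethylene genes with cis-31 (-0.25, 0.21 and downward) and for abscisic acid genes with cis-8 (0.05, -0.07 and downward).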

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

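The tests of the clock genes on 7 dawn genes were written before their values were seen, and the other tests below after the result was seen. Differences between compounds drew a closer look, both in the number of genes past the test and in the gene lists below. The numbers were 1551 between cis-8 and cis-31 and 1748 between endo-8 and cis-31. Camera with its preset correlation called these lists, and an estimated correlation called 0 of them. The test with an estimated correlation also missed a list raised by 1 log2 unit in the simulation, so its 0 calls do not decide.

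Median log2 differences of cis-8 from endo-8 were -1.46 for Aux/IAA and GH3 early auxin genes, -2.30 for SAUR genes, -0.61 for lateral root LBD genes and auxin response factors, -0.29 for auxin transport, -0.49 for ethylene biosynthesis and response, 0.29 for general phenylpropanoid and lignin pathway, 0.46 for flavonoid and anthocyanin pathway, -0.64 for xenobiotic detoxification, 1.04 for morning clock genes, -1.14 for evening clock genes, -0.22 for core hypoxia genes, -0.86 for sugar starvation genes, -0.29 for salicylate defence genes, -0.26 for gibberellin and brassinosteroid metabolism, -0.37 for expansins and xyloglucan endotransglucosylases, 0.78 for mitotic cell cycle, -0.82 for heat shock genes, 0.61 for root markers. In some lists the arrays of one compound lay apart: sugar starvation medians were 0.10 and -0.86 on the cis-8 arrays and 0.30 and 0.53 on the endo-8 arrays, and flavonoid medians -0.15 and 0.75, and -0.21 and -0.42. Differences of cis-8 from cis-31 were -1.06 for Aux/IAA and GH3 early auxin genes, -4.10 for SAUR genes, 1.27 for lateral root LBD genes and auxin response factors, 0.78 for general phenylpropanoid and lignin pathway, 1.12 for flavonoid and anthocyanin pathway, -1.69 for xenobiotic detoxification, 1.93 for morning clock genes, 1.54 for sugar starvation genes, -1.92 for jasmonate biosynthesis and response, 1.08 for salicylate defence genes, -0.71 for abscisic acid and drought genes, -1.002 for expansins and xyloglucan endotransglucosylases, -2.17 for heat shock genes. Those of endo-8 from cis-31 were -2.00 for SAUR genes, 1.86 for lateral root LBD genes and auxin response factors, 0.82 for ethylene biosynthesis and response, 0.44 for general phenylpropanoid and lignin pathway, 0.86 for morning clock genes, 2.43 for sugar starvation genes, -2.06 for jasmonate biosynthesis and response, 1.47 for salicylate defence genes, -0.44 for abscisic acid and drought genes, -1.04 for mitotic cell cycle, -0.84 for heat shock genes, -0.49 for light harvesting and Rubisco small subunit. From the other arrays the cis-31 controls differed by a median of 0.82 for flavonoid, 0.54 for phenylpropanoid and 1.23 for morning clock genes. The treated channel of these lists differed by 0.12, -0.19 and -0.14. For heat shock, jasmonate and sugar starvation genes the controls differed by 0.02, -0.22 and 0.27, and the treated channel by 2.57, 1.87 and -1.68.

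Morning clock genes lay lower on endo-8 array 1 than on cis-8 array 1, and higher in the controls of cis-31 than in the other controls. Another time of day at collection may account for both: dawn genes outside the lists differed by a median of -1.58 on the treated side (7 of 7 lower), and by 1.93 in the control channel (7 of 7 higher). An effect of endo-8 stays open: in replicate 2 the morning list differed by a median of -0.20 with members on both sides (LHY -1.31, CCA1 -0.92, RVE2 0.64), and the evening list by 0.82. A swap of labels between endo-8 array 1 and a cis-8 array was excluded by the SAUR median of 2.05 on endo-8 array 1. This pattern was narrowed to the morning genes after the evening genes were seen to differ in replicate 2 as well, and AT4G33980, one of the evening genes, had already been seen.

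A total of 183 genes were called in opposite directions with cis-31 and with cis-8 or endo-8, 45 of them higher with cis-31. A difference of the control seedlings alone would put most of the difference in the control channel, which carried a median of 38.3% of it. That share compares channel signals between slides and scans. It therefore excludes the controls as the only source only if slide and scan left the treated channel unchanged. The third quartile was 52.0%, so for some of the genes the controls carried most of it. A slide or scan effect stays open: 8.74% of the genes differed the same way in both dyes, but a shift of both alike cancels in the ratio on which the genes were chosen. An effect of cis-31 itself could not be told from its slide, because the number of slides that hold cis-31 was 1.

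The 2 cis-31 arrays lay close to each other. Whether they carry the same extracts stays open, since the SD of their difference, 1.02 times that of repeated spots, is how the closeness was seen. Lying on 1 slide does not by itself bring arrays this close, since the SD within cis-8 or endo-8, on the other slide, was at least 2.97 times as large.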

How the results depend on the processing

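Counting the cis-31 arrays as 1 sample was chosen after seeing the data, and the design written before treated them as 2. With 2 samples the counts were 10820 for cis-31, 4120 for cis-8, 6694 for endo-8, 10487 for the mean, 74 between cis-8 and endo-8, 8885 between cis-8 and cis-31 and 9731 between endo-8 and cis-31; the fit then has 1 more residual degree of freedom. Camera called 98 of 175 list results, an estimated correlation 0 and fry 37. The estimated correlation also missed the list planted in the simulation, so its 0 calls do not decide. The scanner's processed signals gave 90 genes for cis-8, 1287 for endo-8, 834 between cis-8 and cis-31 and 561 between endo-8 and cis-31, with r = 0.126 for cis-31 and endo-8. Median centring gave 5484 for cis-8, 9292 for endo-8, 9282 for the mean and 2721 between endo-8 and cis-31. For cis-8, no filter gave 482, the stricter filter 103 and a trended robust prior 144. The deposited series table gave 1482 for cis-31, 8 for cis-8, 1086 for endo-8, 696 between cis-8 and cis-31 and 420 between endo-8 and cis-31. By limma the arrays of cis-8 alone gave 0 (5898 at an unadjusted p under 0.05) and those of endo-8 alone 1048; cis-31 alone left no residual degrees of freedom. Leaving out 1 array gave 1192 to 2652 for cis-31, 0 to 302 for cis-8, 0 to 2318 for endo-8, 1090 to 4309 for the mean, 0 to 1622 between cis-8 and cis-31 and 0 to 1963 between endo-8 and cis-31. Over the same fits r was 0.522 to 0.699 for cis-8 and endo-8, 0.0703 to 0.109 for cis-31 and endo-8 and -0.104 to 0.113 for cis-31 and cis-8. Between cis-8 and endo-8 limma called 0 in each of those fits and on slide 2 alone (2994 at an unadjusted p under 0.05). With a replicate block the counts were 3698 for cis-31, 1622 for cis-8, 3930 for endo-8, 5602 for the mean, 2772 between cis-8 and cis-31, 3371 between endo-8 and cis-31 and 0 between cis-8 and endo-8. By the labels the arrays share only a number, but control channels of cis-8 and endo-8 arrays of one number differed little (SD 0.104 and 0.112). Deviations of arrays with one number correlated at 0.391 for cis-8 and endo-8, -0.000478 for cis-31 and cis-8 and 0.0314 for cis-31 and endo-8. Of 423 gene and 98 list results 0 reversed, and between 0 and 235 gene calls were lost under a setting. A list counted as reversed only where the other direction passed at an adjusted p under 0.05. The results followed were called ones of the same arrays, so the lack of reversals was likely from the start. The deposited series table, the stricter filter and the fits of 1 compound or slide were not checked by gene or list, nor the trended robust prior by list. Fits without a cis-8 or endo-8 array have fewer residual degrees of freedom, those without a cis-31 array do not, and the cause of the other changes was not tested.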

Other observations

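Some genes of the nutrient supply list stood apart between arrays of one compound. PPsPase1, a phosphatase gene induced by phosphate starvation, was at -0.17 and 3.168 on the cis-8 arrays and at 0.63 and 4.17 on the endo-8 arrays. The galactolipid synthesis gene MGD3 was at -1.42 and 1.46 on the cis-8 arrays and at -2.14 and 2.63 on the endo-8 arrays, and PECP1 at 0.70 and 2.46 and at 0.18 and 2.87. Each of these genes was higher on array 2 than on array 1 with both compounds, so the values went with the array number. Control RNA of cis-8 and endo-8 arrays of one number differed little. The genes were picked out after their values were seen, and no test was made of them.

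DFR, an anthocyanin pathway gene, was at 3.62 on cis-8 array 2 and between -0.45 and 1.05 on the other 5 arrays, and LDOX at 2.39 and between -0.52 and 0.07. UGT79B1 was at 3.14 on that array and between -0.74 and 0.20 on the others. These genes too were picked out after their values were seen, without a test.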
